A study of Homo sapiens with 6 samples.

How the data were processed

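Poly(A) RNA of 6 libraries, labelled as PANC-1, a human pancreatic carcinoma cell line, was sequenced: 3 libraries labelled as controls and 3 labelled as treated with extracellular vesicles (EVs) derived from cancer-associated fibroblasts (CAFs). The groups are called control-labelled and EV-labelled below. Per the labels' protocols, the poly(A) RNA was captured on oligo(dT) beads, and the second cDNA strand was made with uracil and removed, which keeps the strand of origin. Whether the counting used the strand is not given in the sources used here. The submitters' processing notes name TopHat, RSEM and the hg19 build, without versions or the step each was used for, and the annotation release is not given in the sources used here. No coordinates are printed, because the files give none. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

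The authors deposited a table of raw counts per gene, whole numbers for 32453 features in the 6 libraries. Of these, 375 features carried only an assembly number (MSTRG) and no gene name. They held 0.099% to 0.134% of the counts of a library and were left out, which left 32078 genes. The authors also deposited a table of their own comparison, with mean log2 abundance per group, log2 fold change, p-values and q-values. Its direction was read from its own group means.

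Total counts per library were 23646239, 27535620 and 27250982 in the control-labelled libraries and 27134375, 21669757 and 24809641 in the EV-labelled libraries. A count of 0 allows up to 3 counts, which is 0.109 to 0.139 CPM, counts scaled to a common library size, depending on the library. Such floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. The 10 most abundant genes took 5.61% to 6.12% of the counts of a library. No pair of libraries held counts that agreed within sampling noise, so all 6 were counted.

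Genes were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (glmQLFit and glmQLFTest), TMM scaling factors and the filter of filterByExpr, and Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p under 0.05. All adjusted p-values of single genes come from this test unless another is named. Fold changes are EV-labelled over control-labelled, as fitted by edgeR with a prior count of 0.125. The SE is the fitted log2 coefficient divided by the square root of F. CPM values used the TMM factors and are given as mean ± SD over 3 libraries. Of the tested genes, 99.26% had a GC content, a length and a gene type in GENCODE v29, which is built on GRCh38 and was used only for these properties.

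Before the data were examined, 43 gene lists were fixed, covering pathways, markers of other cell types and signs of RNA quality. Lists with at least 5 tested genes, 39 of them, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated from the libraries was run beside it. Named genes followed a rule fixed at the same time. Considered first were called genes with a mean of at least 1 CPM and no overlap between the libraries of the groups. From these it took the 8 with the highest and the 8 with the lowest fold change, and the 4 with the lowest adjusted p in each direction. It added up to 4 called members with the lowest adjusted p per list (2 where none was called). It always named CDH1, VIM, FN1, ZEB1, MKI67, MYC, CXCL8, IL6, COL1A1 and ACTA2. Some genes that this rule takes, or that are exceptions to a count, are not reported here by name. Members named as the exceptions to a count are outside this rule and were chosen after their values were seen.

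The test was checked on simulated counts drawn for the 14670 tested genes, of which 50 each were changed by 1.25-, 1.5-, 2- and 4-fold. It called 68%, 70%, 86% and 92% of these, and 10 of the 14470 unchanged genes, which made 5.95% of its calls false. Far fewer genes were changed in the simulation than were called in the data. It therefore does not check scaling or false calls where many genes shift. The list test called a shifted list and 0 of 20 random lists. Simulated genes were drawn independently, so this check could not show false calls that arise from correlation between members of a list. In the data that correlation was estimated at 0.411 for the ATF4 list.

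The alternatives were median-ratio, upper-quartile and library-total scaling, no count filter, a filter of 1 CPM in 3 libraries, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom, stricter thresholds, protein-coding genes alone, and other list tests. Keeping the MSTRG loci and a loess correction for GC content and length in each library were added after the data were seen.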

Results

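The data were counts per gene from 6 libraries that the labels assign to PANC-1, 3 labelled as controls and 3 labelled as treated with EVs derived from CAFs, the activated fibroblasts of tumour stroma. PANC-1 is an established line from a human pancreatic carcinoma, and whether the cells are that line was not tested. Totals ranged from 21669757 to 27535620 counts. The comparison asked which transcripts differed between cells given these vesicles and cells that were not. The protocol text describes vesicle treatment in the same words for every library, controls included, so the groups rest on the titles and treatment labels, and vesicle dose and time are not given in the sources used here.

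In the EV-labelled libraries, 24 of 25 listed genes of the amino acid and integrated stress response were lower and 28 of 30 of DNA replication were higher. Both lists passed camera at its preset correlation but not with an estimated one (adjusted p = 0.118 with an estimated correlation for each). TRIB3, a pseudokinase induced by that response, was at 96.6 ± 5.79 CPM against 491 ± 74.0 CPM in the control-labelled libraries (SD, n = 3 each), a log2 fold change of -2.35 ± 0.09 (SE; adjusted p = 1.2e-12). CTH, an enzyme of cysteine synthesis, was 4.17-fold lower and SESN2, a stress-induced inhibitor of mTORC1 signalling, was 4.08-fold lower. FEN1, the flap endonuclease of lagging-strand synthesis, was at 160 ± 7.80 against 75.1 ± 10.9 CPM (log2 fold change 1.09 ± 0.08, adjusted p = 5.67e-09). Of 14670 tested genes, 6001 (40.91%) changed, 2965 higher and 3036 lower in the EV-labelled libraries. Most changes were small: 126 genes were at least 2-fold higher and 433 at least 2-fold lower.

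**Figure D1:**
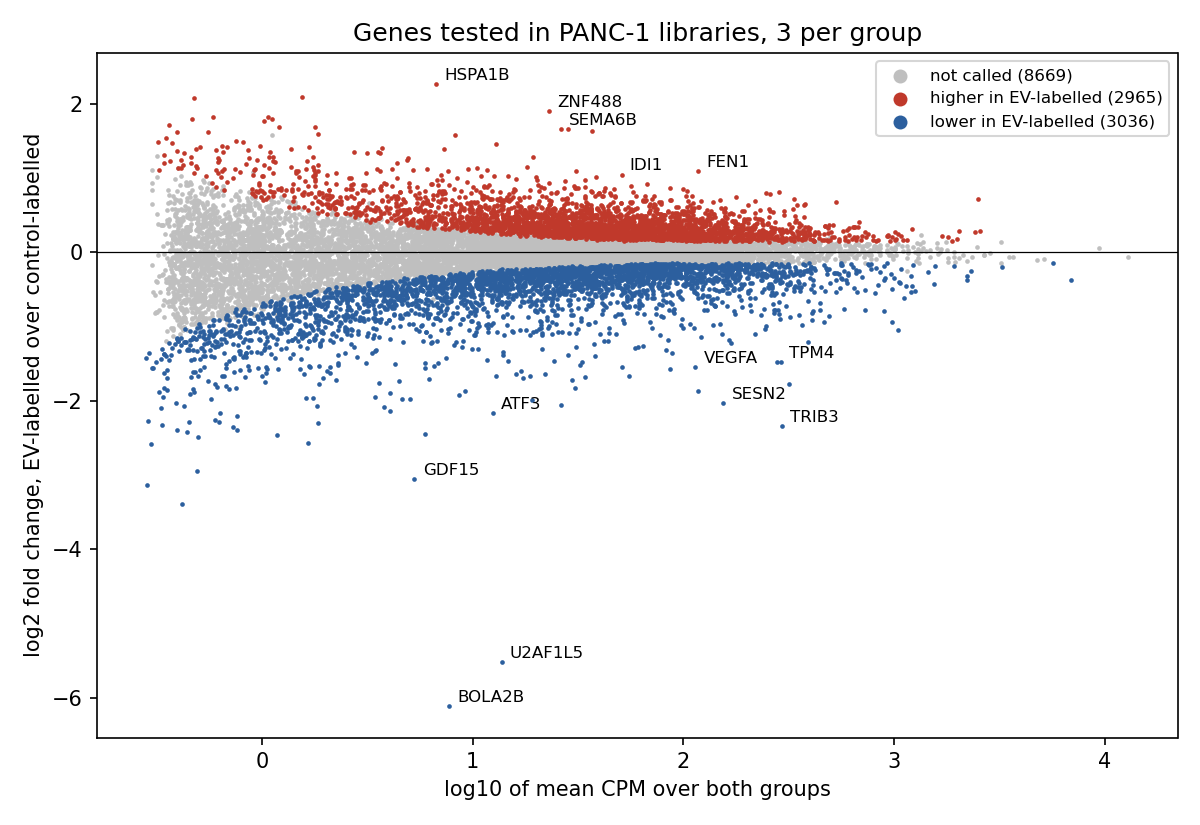
Log2 fold change, EV-labelled over control-labelled, against the log10 of the mean CPM over both groups, 1 point per tested gene. Red points are the 2965 genes called higher, blue points the 3036 called lower and grey points those not called; BOLA2B and U2AF1L5 lie far below all other genes.

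Among the 8 genes with the highest fold change was HSPA1B, an inducible HSP70 chaperone (log2 fold change 2.26 ± 0.17, adjusted p = 7.08e-09), whose reads are hard to separate from those of its near-identical copy HSPA1A. HSPA1A rose too, from 18.1 ± 3.07 to 56.0 ± 10.3 CPM (1.63 ± 0.12, adjusted p = 6.37e-09), so a move of reads between these 2 genes does not account for the rise. ZNF488, a zinc finger protein, rose from 9.74 ± 0.702 to 36.3 ± 1.54 CPM (log2 fold change 1.90 ± 0.09), and SEMA6B, a transmembrane semaphorin, from 12.6 ± 2.03 to 39.8 ± 5.65 CPM (1.66 ± 0.11). BAMBI, a pseudoreceptor that dampens TGF-beta and BMP signalling (2.09 ± 0.27), ABCG4 (1.82 ± 0.31), RHBDL3 (1.80 ± 0.30), TTPA (1.76 ± 0.29) and TSPAN18 (1.68 ± 0.29) also rose, but stayed at 2.74 CPM or below in the EV-labelled mean (TSPAN18). FAM111B (1.65 ± 0.11) and APLN, which encodes the ligand apelin (1.45 ± 0.10), were among the 4 higher genes with the lowest adjusted p.

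Among the 8 genes with the lowest fold change were GDF15, a stress-induced cytokine (-3.06 ± 0.26, adjusted p = 3.5e-08), PAPPA2, a protease of insulin-like growth factor binding proteins (-2.57 ± 0.27), NUPR1 (-2.44 ± 0.19) and ATF3 (-2.17 ± 0.12), both stress-induced regulators of transcription. TPM4, a tropomyosin, fell from 426 ± 17.1 to 153 ± 4.32 CPM (-1.48 ± 0.06, adjusted p = 1.93e-12). BOLA2B (-6.12 ± 0.90), U2AF1L5 (-5.52 ± 0.39) and NPIPA9 (-2.30 ± 0.48) have near-identical copies and are uncertain. Without control replicate 1, NPIPA9 was at -1.39 (adjusted p = 0.0043). BOLA2B was at 0.686, 23.7 and 21.3 CPM in the control-labelled libraries, so its control mean rested on 2 of them, and limma-voom did not call it (-5.07, adjusted p = 0.0702).

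The list of ATF4 and amino acid response genes had 24 of 25 members lower, with a median log2 fold change of -0.86 (camera adjusted p = 4.59e-60; adjusted p = 0.118 with an estimated correlation). It included the cystine transporter gene SLC7A11 (-1.83 ± 0.09) beside TRIB3, CTH and SESN2, and ATF5, at 0.05, was its only member not called. Growth factor immediate early and MAPK feedback genes were lower in 23 of 25 (median -0.80, adjusted p = 2.15e-20; adjusted p = 0.118 with an estimated correlation). These included ATF3, the AP-1 subunit gene JUN (-0.82 ± 0.06), IER2 (-1.09 ± 0.08) and AREG, which encodes the EGF receptor ligand amphiregulin (-1.28 ± 0.10). Of the hypoxia and HIF1 targets, 13 of 17 fell (adjusted p = 2.73e-11; adjusted p = 0.118 with an estimated correlation). VEGFA (-1.55 ± 0.08), DDIT4 (-1.78 ± 0.11), NDRG1 (-1.47 ± 0.08) and ANGPTL4 (-1.26 ± 0.06) had the lowest adjusted p among them. For all 3 lists the number of lower members was the same adjusted over the list alone, which added 1 higher member among the hypoxia genes.

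**Figure D2:**
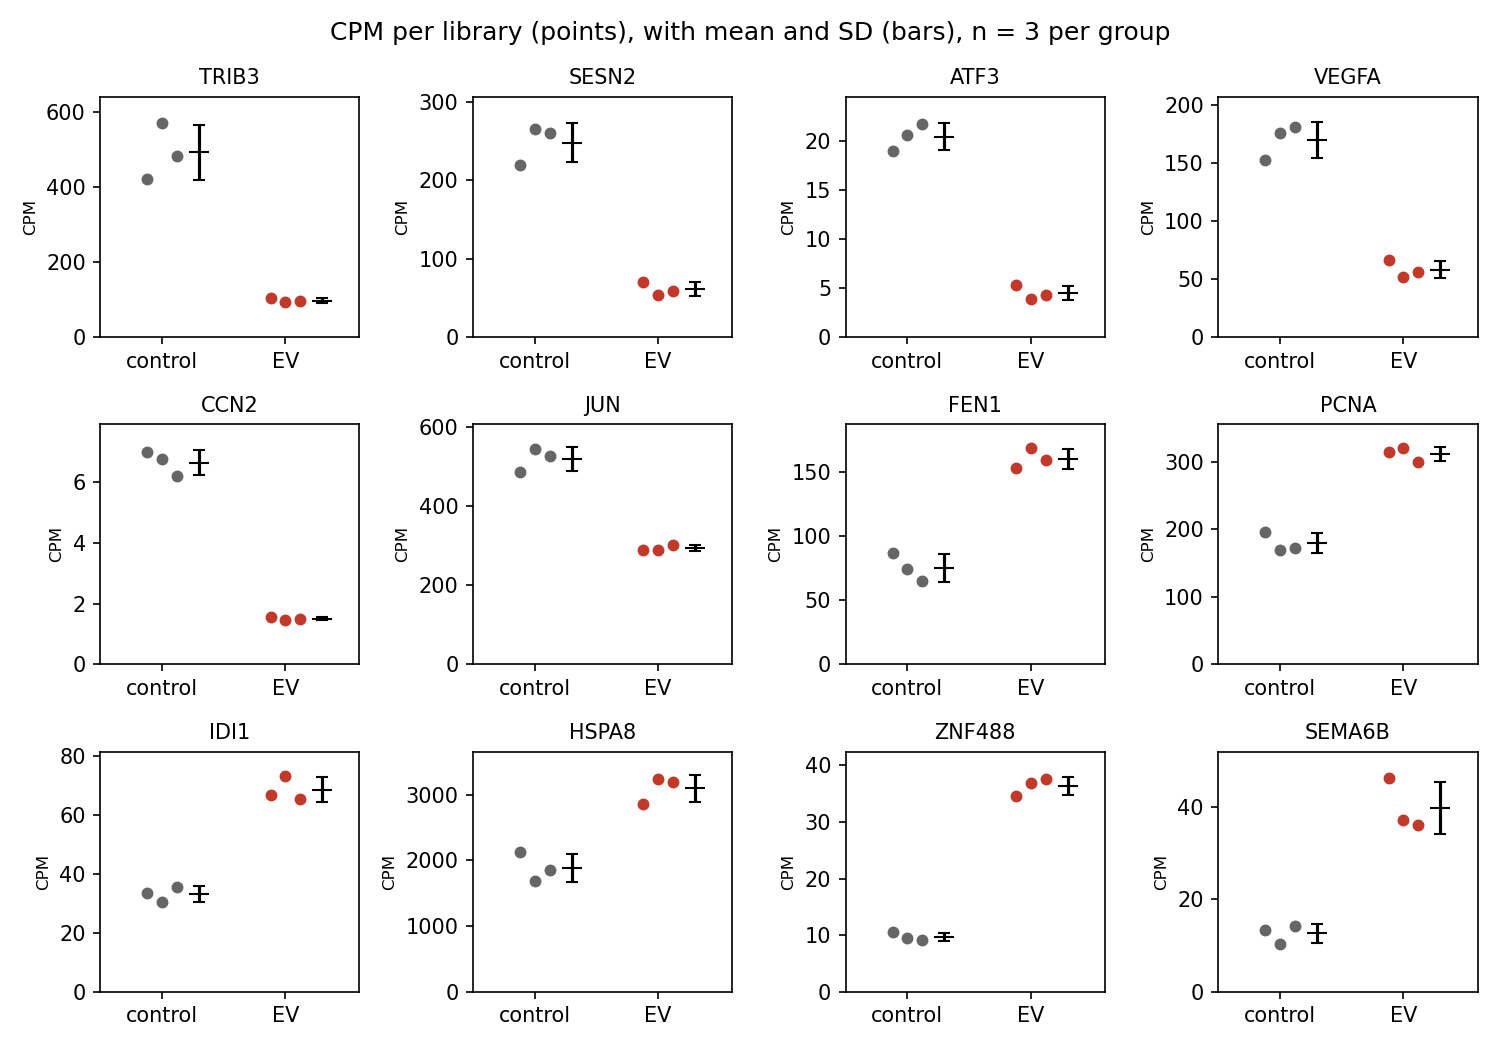
CPM of 12 genes per library, on linear axes that start at 0, with grey points for control-labelled and red points for EV-labelled libraries; the bar beside them is the mean ± SD of the 3 libraries. In every panel the groups do not overlap, which held for 50.63% of all tested genes (10% expected by chance). The panels were picked from the named genes, for some of which no overlap was a condition. TRIB3 lies at 92.2 to 103 CPM in the EV-labelled libraries and at 422 to 569 CPM in the control-labelled libraries.

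Genes of proliferation were higher. In the S phase and DNA replication list 28 of 30 members rose, with a median log2 fold change of 0.55, and the count was the same adjusted over the list alone (camera adjusted p = 2.49e-25; adjusted p = 0.118 with an estimated correlation). GINS1 (0.98 ± 0.07) and CDC6 (0.86 ± 0.07), which act in replication initiation, and PCNA, the polymerase clamp (0.80 ± 0.06), were among those with the lowest adjusted p. In the mitosis list 20 of 29 members rose, 24 adjusted over the list alone, with a median of 0.37 (adjusted p = 1.52e-12; adjusted p = 0.251 with an estimated correlation). They included AURKA (0.67 ± 0.06), CDK1 (0.62 ± 0.07), CCNA2 (0.57 ± 0.06) and KIF20A (0.57 ± 0.06). MKI67, which encodes the Ki-67 antigen, was at 534 ± 60.1 against 462 ± 64.3 CPM and did not pass (0.21 ± 0.09, adjusted p = 0.0562). It passed in 7 of 16 other settings, among them without control replicate 1 (adjusted p = 0.00287), without EV replicate 1 (adjusted p = 0.0179), with library totals alone (adjusted p = 0.0415), without a count filter (adjusted p = 0.00141), with limma-voom (adjusted p = 0.0498) and after the GC content and length correction (adjusted p = 0.000309).

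Cholesterol synthesis and uptake genes rose in 16 of 22, among them IDI1 (1.04 ± 0.07), MSMO1 (0.81 ± 0.09), HMGCS1 (0.76 ± 0.08) and HSD17B7 (0.75 ± 0.07), while 1 member fell. The list passed camera (adjusted p = 5.91e-10; adjusted p = 0.246 with an estimated correlation). Of the heat shock and chaperone list, fixed as a sign of RNA quality and handling, 12 of 17 rose, and HSF1 fell (adjusted p = 4.28e-08; adjusted p = 0.271 with an estimated correlation). HSPA8 was at 0.72 ± 0.07 and DNAJA1 at 0.64 ± 0.06 on the log2 scale. The counts of both lists were the same adjusted over the list alone. The other RNA quality lists did not pass, namely mitochondrially encoded genes (2 higher and 1 lower of 13, adjusted p = 0.757) and histone genes (3 higher and 3 lower of 13, adjusted p = 0.833). Nuclear-encoded oxidative phosphorylation genes rose in 27 of 40, 29 adjusted over the list alone (adjusted p = 4.83e-05; adjusted p = 0.423 with an estimated correlation). COX6B1 was at 0.39 ± 0.06 and NDUFA2 at 0.42 ± 0.08, while 2 members, among them NDUFA13, fell.

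**Figure D3:**
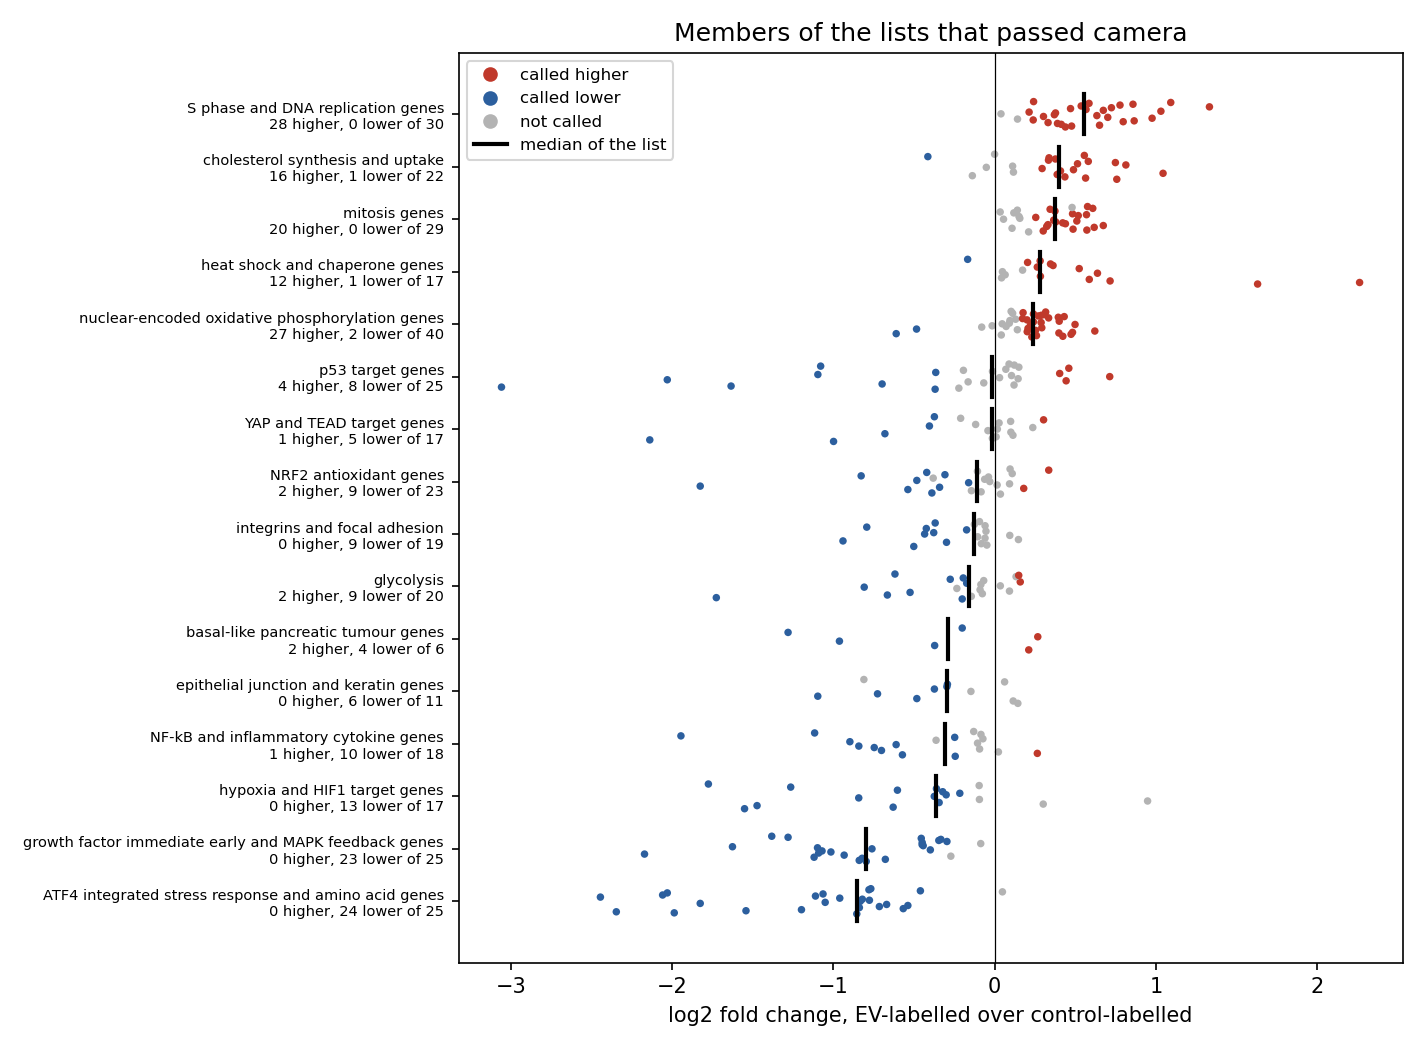
Log2 fold change, EV-labelled over control-labelled, of each tested member (points) of the 16 lists that passed camera, with the list median as a black bar. Red and blue points are members called higher and lower, grey points those not called; the lists at the top and bottom, S phase and ATF4, have medians of 0.55 and -0.86.

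Lower lists of inflammation, metabolism and adhesion were more mixed. NF-kB and cytokine genes fell in 10 of 18, 11 adjusted over the list alone, and NFKBIA rose (adjusted p = 4.83e-05; adjusted p = 0.365 with an estimated correlation). CSF3 (-1.95 ± 0.19), TRAF1 (-1.12 ± 0.13), LIF (-0.84 ± 0.07) and CXCL8, which encodes interleukin-8 (-0.61 ± 0.11), were lower. Glycolysis genes fell in 9 of 20 and rose in 2, PGAM1 and SLC16A1, or 10 and 3 adjusted over the list alone (adjusted p = 0.00187; adjusted p = 0.365 with an estimated correlation). The glucose transporter gene SLC2A3 (-1.73 ± 0.10) and the hexokinase gene HK2 (-0.67 ± 0.07) were lower. Integrin and focal adhesion genes fell in 9 of 19, the same adjusted over the list alone (adjusted p = 2e-04; adjusted p = 0.33 with an estimated correlation). They included ITGB4 (-0.94 ± 0.07) and ITGA3 (-0.50 ± 0.06). Epithelial junction and keratin genes fell in 6 of 11 tested and 22 listed, and 1 was higher adjusted over the list alone (adjusted p = 0.000717, and adjusted p = 0.251 with an estimated correlation). The lower ones included the claudin genes CLDN1 (-1.10 ± 0.06) and CLDN4 (-0.73 ± 0.06) and KRT19 (-0.48 ± 0.06).

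In 4 further lists the call rested on a minority of strongly lower members or on few genes. Of the p53 targets 8 fell, 9 adjusted over the list alone, and 4 rose among 25, with a median of -0.01 (adjusted p = 0.00456; adjusted p = 0.251 with an estimated correlation). Its lower members GDF15, SESN2, BBC3 (-1.63 ± 0.11) and GADD45A (-1.10 ± 0.08) are known to respond to other stresses too. The call was lost on ranks (adjusted p = 0.574) and without genes held by other lists too (adjusted p = 0.0676). YAP and TEAD targets fell in 5 of 17, and FJX1 rose, with a median of -0.01 (adjusted p = 0.0195; adjusted p = 0.271 with an estimated correlation), and the call was lost on ranks (adjusted p = 0.326). CCN2 was at -2.14 ± 0.16 on the log2 scale, and CCN1 fell from 329 ± 19.9 to 165 ± 9.76 CPM. NRF2 antioxidant genes fell in 9 and rose in 2, TXN and GSR, of 23 (adjusted p = 0.0298; adjusted p = 0.251 with an estimated correlation). This call was lost without EV replicate 1 (adjusted p = 0.0508), on ranks (adjusted p = 0.108) and without genes held by other lists too (adjusted p = 0.772). Of 6 basal-like tumour genes tested, from 24 listed, 4 fell, including KRT15 (-0.96 ± 0.08), and 2 rose, UCA1 and CTSV (adjusted p = 0.015, and adjusted p = 0.251 with an estimated correlation). The call was lost on ranks (adjusted p = 0.326), and only 4 of the 6 are in no other list. UCA1 did not pass without EV replicate 2 (adjusted p = 0.0655).

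The mesenchymal and EMT list did not pass (4 lower and 1 higher of 8 tested and 20 listed, adjusted p = 0.255), although VIM (-0.37 ± 0.05), ZEB1 (-0.46 ± 0.07) and AXL (-0.40 ± 0.07) fell. Most of that list could not be tested, and CDH2, TWIST1 and PRRX1 had 0 counts in all libraries. FN1 was at 0.694 ± 0.166 against 0.474 ± 0.0727 CPM (0.56 ± 0.34, adjusted p = 0.203). TGF-beta targets had 5 higher and 7 lower of 17 (adjusted p = 0.407), with BHLHE40 at 23.9 ± 1.65 against 46.8 ± 4.28 CPM (-0.97 ± 0.08) and ID2 at 1.39 ± 0.14. MYC fell from 419 ± 13.2 to 293 ± 16.2 CPM (-0.52 ± 0.06). Interferon genes rose in 9 and fell in 1, MX2, of 22 (adjusted p = 0.0646), with IFIT1 at 0.85 ± 0.09. That list passed without EV replicate 3 (adjusted p = 0.0274), without a count filter (adjusted p = 0.0229) and on ranks (adjusted p = 0.0473). Antigen presentation and checkpoint genes had 3 higher and 5 lower of 14 (adjusted p = 0.188), with the MHC class II pathway genes HLA-DRA (-1.78 ± 0.27) and CD74 (-1.73 ± 0.24) among the lower ones. Their control-labelled means were 2.90 and 3.46 CPM.

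The remaining lists did not pass camera. Numbers higher and lower are given in that order. The gemcitabine handling list had 9 and 4 of 21, ferroptosis 5 and 5 of 15, stem cell associated genes 0 and 3 of 8 (CD44, SOX9 and KLF4), and ribosomal proteins 12 and 1 of 40, all at an adjusted p = 0.188. Without EV replicate 2, CD44 did not pass (adjusted p = 0.0547). Ribosomal proteins passed without EV replicate 3 (adjusted p = 0.0126), without a count filter (adjusted p = 0.0416) and after the GC content and length correction (adjusted p = 0.0435). Angiogenic factors had 5 and 6 of 17 (adjusted p = 0.213) and matrix genes and proteases 2 and 4 of 13 (adjusted p = 0.23). Notch targets had 3 and 2 of 10 (adjusted p = 0.255), the unfolded protein response 4 and 7 of 22 (adjusted p = 0.289), and fatty acid synthesis 8 and 4 of 21 (adjusted p = 0.444). Vesicle biogenesis and uptake genes had 5 and 7 of 25 (adjusted p = 0.757), and MYC and ribosome biogenesis 7 and 6 of 27 (adjusted p = 0.833). JAK-STAT3 targets had 4 and 4 of 14 (adjusted p = 0.833), autophagy and lysosome genes 8 and 9 of 29 (adjusted p = 0.836), axon guidance genes 4 and 5 of 15 (adjusted p = 0.874) and Wnt targets 2 and 3 of 10 (adjusted p = 0.954). Adjusted over the list alone, these became 5 and 0 for ribosomal proteins, 6 and 5 for ferroptosis, 6 and 7 for angiogenic factors, 4 and 2 for Notch targets and 10 and 5 for fatty acid synthesis. They became 6 and 7 for vesicle genes, 9 and 6 for MYC and ribosome biogenesis and 5 and 5 for axon guidance, while antigen presentation genes had 3 and 6. The other counts were the same. Median, mean and test differed in sign for the TGF-beta, stem cell, angiogenic, matrix, mitochondrially encoded, autophagy, axon guidance and Wnt lists.

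Among markers of other cell types, fibroblast markers had 2 higher and 2 lower of 9 tested (adjusted p = 0.937). COL1A2 (0.71 ± 0.07) and COL5A1 (1.62 ± 0.40) rose, and COL6A3 (-0.61 ± 0.06) and ACTA2 (-0.91 ± 0.17) fell. COL1A1 had 1 to 3 counts in each library, and CDH1 and IL6 had 0 counts in all 6, which allows up to 0.139 CPM. Neuronal and Schwann cell markers had 2 higher and 1 lower of 5 (adjusted p = 0.998). Too few members were tested for camera among classical tumour genes (1 of 28 listed, not called), immune cell markers (4 of 24, of which CD8A fell), endothelial markers (3 of 14, not called) and acinar and endocrine markers (1 of 16, not called).

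The authors' deposited table held 24724 genes, 857 marked up and 313 marked down. Its fold changes are control-labelled over EV-labelled. All 857 genes marked up in the authors' deposited table had the higher mean in the control-labelled libraries. TRIB3, for example, has a log2 fold change of 2.33 in the authors' deposited table. Of the marked genes, 341 had a q of at least 0.05 in the authors' deposited table. Among 14664 genes in both, 5658 were called by the authors' q and by edgeR, all in the same direction once the sign was turned, 62 by the authors' deposited table alone and 342 by edgeR alone. Both comparisons rest on the same libraries, and their log2 fold changes correlated at 1 after rounding (Pearson and Spearman, sign turned). The shared direction is therefore no independent support. Directions given here follow the sample labels.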

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

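The test of exchanged labels was chosen after the deposited comparison's direction was seen, and its condition that carried-over transcripts be detectable was added after the counts were seen.

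Assembled loci without a gene name were left out of the comparison. Tested in the same way, 11 of 216 such loci were higher in the EV-labelled libraries than in the controls, and 70 were lower.

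Amino acid response, immediate early and hypoxia lists were lower, and replication, mitosis, sterol and heat shock lists higher, in the EV-labelled libraries, but with an estimated correlation 0 lists were called (lowest adjusted p = 0.118). The estimate was below the preset 0.01 for the NRF2 list (0.00243), yet its camera adjusted p rose from 0.0298 to 0.251. For the BMP and SMAD list, chosen after the data were seen, the estimate was 0.00924, and the camera adjusted p rose from 0.000811 to 0.0575. A higher correlation between members is therefore not the only reason that calls were lost. A bias of GC content and transcript length as the whole cause is argued against: after a correction in each library, 16 of the 16 called lists kept their call and direction at the preset correlation, although the medians of 2 changed sign. The real grouping gave 6001 changed genes and the highest of the other splits gave 0. For lists the values were 16 and 12. In each case 1 of the 10 splits, the real one, reached the real value, and 10 splits are too few for a share under 0.05. Every other split also mixes libraries of both groups. The real difference then widens the spread within its sets and partly remains between them. The values 0 and 12 are therefore not levels that chance alone would give. An effect of the vesicles, and a difference in culture or handling between the groups, stay open, since no table here separates them.

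The copies BOLA2B, U2AF1L5, EIF3CL and NPIPA9 were among the genes lower in the EV-labelled libraries; EIF3CL, chosen after its value was seen, was at -1.92 ± 0.44, but at -0.75 without control replicate 2, and NPIPA9 was at -2.30 ± 0.48, but at -1.39 without control replicate 1. If reads had only moved between copies, the partners would rise and the sum of a copy and its partners would hardly change. The sum kept 13.2% of the log2 fold change for EIF3CL (-7.80% to 31.2% with 1 library left out), 35.4% for NPIPA9 and 55.6% for U2AF1L5, a median of 35.4% (29.7% to 47.0%), between the bounds set beforehand, and BOLA2B had no partner of its name to add. The partners of NPIPA9 fell (-0.57 ± 0.12, adjusted p = 0.000889), and U2AF1 was at -0.31 ± 0.17 (adjusted p = 0.148) while its sum with U2AF1L5 fell (-3.07 ± 0.25, adjusted p = 1.87e-08), so for these 2 copies a move to the partners is argued against as the whole cause. For EIF3CL, whose partner was at 0.23 ± 0.24 (adjusted p = 0.466), a move stays open, as do, for all 4, reads left uncounted because they match several copies.

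The deposited comparison counts genes higher in the control-labelled libraries as up. The ratio may simply have been written as control over treated, and exchanged group labels could be another reason. The sign alone cannot tell these apart. The deposited group means follow the same labels as the counts, with TRIB3 at 8.92 in the control-labelled and 6.60 in the EV-labelled mean (log2). If vesicles carried fibroblast mRNA into the cells, markers that the line lacks would be higher in the treated group. The 8 fibroblast markers below the count filter summed to 32 counts in the control-labelled and 10 in the EV-labelled libraries (exact binomial p = 0.00168, two-sided), the direction exchanged labels would give. But 21 of the 32 and 2 of the 10 counts came from PDGFRB, and COL1A1 went the other way, with 5 against 8 counts. COL5A1, a low marker above the filter, also went the other way, at 0.265 ± 0.083 CPM in the control-labelled and 0.847 ± 0.299 CPM in the EV-labelled libraries. Of the 9 markers above the filter, 2 rose and 2 fell. The binomial test treats reads as independent molecules and leaves out the spread between libraries. Also, 5 of the 8 markers, DCN and LUM among them, had 0 counts in all libraries, so carry-over itself was not seen. Counts this near the floor decide nothing, and the question whether the labels were exchanged stays open.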

How the results depend on the processing

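Keeping the MSTRG loci and the correction for GC content and length were chosen after the data were seen. The number of changed genes, 6001, stayed within 1.5 times under other scalings, count filters, tests and gene sets (5197 with DESeq2, 6651 with the GC content and length correction, which gave 58.3% higher genes against 49.4%, and upper-quartile factors 45.3%) and ranged from 4756 to 5612 with 1 library left out. It was 351 against a fold of 1.5 and 559 with a fold of at least 2, where the threshold itself asks for more; the share of higher genes was then 21.4% and 22.5%. The replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.0209, -0.00895 and -0.0107, none best with its own number. With the replicate number as a block, 5743 genes and 16 lists were called, and MKI67 passed (adjusted p = 0.0421). Of the lists, 15 to 18 were called with 1 library left out. With an estimated correlation 0 were called, with a lowest adjusted p of 0.118, and fry called 26, since it does not compare a list with other genes. On ranks 13 were called, 12 of them among the 16; p53, YAP and TEAD, NRF2 and basal-like lists were lost and interferon genes gained. Without genes held by several lists 13 of the 16 remained; p53 (0.0676) and NRF2 (0.772) were lost and basal-like genes were too few to test. Ribosomal proteins were gained without EV replicate 3, without a count filter and with the GC content and length correction, interferon genes in the first 2 of these and on ranks. Agreement with the authors' deposited table was 5658 genes at q under 0.05 and 550 with a fold of at least 2 as well, a smaller set by construction. That table rests on the same libraries, so the agreement is not an independent check. Of 166 named genes no direction turned for a called gene, and the fold of a named gene moved by over 1.5 times only for NPIPA9 without control replicate 1 and BOLA2B with limma-voom; 25 calls changed over 16 settings, mostly of MKI67, MT-ND6 and ribosomal protein genes near the threshold. Depth limits genes near 3 counts per library. Of the list members, 210 were below the count filter, 79 of them with 0 counts. Others below the filter had more than 3 counts, such as BST2 with 5 to 15 per library.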

Other observations

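The gene lists here were chosen after the data were seen, except that the prediction for the tRNA synthetases was written before their classes were compared. Camera was adjusted over these 7 lists.

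Homologous recombination and crosslink repair genes rose in 14 of 17 in the EV-labelled libraries (adjusted p = 3.47e-06; adjusted p = 0.0605 with an estimated correlation), among them FANCM (0.89 ± 0.13) and BRIP1 (0.71 ± 0.09). BMP and SMAD targets rose in 7 of 9 tested and 13 listed (adjusted p = 0.000811; adjusted p = 0.0575 with an estimated correlation), with BAMBI at 2.09 ± 0.27, SMAD6 at 1.33 ± 0.18 and ID2 at 1.39 ± 0.14, while ID1 fell (-0.30 ± 0.06). Of the 7, 5 (BAMBI, SMAD6, ID2, ID3 and NOG) are also in the fixed TGF-beta list, which did not pass, so the lists are not independent. Of 17 listed squamous lineage genes only 5 could be tested, and these 5 fell (adjusted p = 3.07e-12; adjusted p = 0.0575 with an estimated correlation). TP63, the master regulator of that lineage, was at 76.0 ± 5.76 against 167 ± 8.14 CPM (SD, n = 3 each), and KRT13 was at -2.08 ± 0.18 on the log2 scale. ITGB4 and KRT15 are also in fixed lists. Of the untested ones, KRT16 had 2 to 14 counts per library, and KRT14 and TRIM29 had at most 2 counts in any library. KRT6A, KRT6B, DSC3, SERPINB5 and PKP1 had 0 in all, and KRT5 and DSG3 are not in the count table under these names. Fibroblast transcripts of high abundance had 1 higher, COL1A2, and 3 lower, COL6A2, COL6A3 and VIM, of 8 tested and 12 listed (adjusted p = 0.779).

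A hypothesis was that the lower amino acid response genes follow known targets of the integrated stress response rather than all genes of tRNA charging. All 13 cytosolic tRNA synthetase genes listed as targets were lower, with a mean log2 fold change of -0.51 (SD 0.28; adjusted p = 3.28e-14 for the list; adjusted p = 0.0575 with an estimated correlation), and CARS1 was the lowest (-1.02 ± 0.06). Of the 7 other cytosolic ones 0 were lower and 2, FARSB and RARS1, were higher, with a mean of 0.10 (SD 0.17; adjusted p = 0.246). The difference was -0.62 (exact permutation p = 5.16e-05 over 77520 splits, two-sided; genes are not independent replicates). Of the 13 targets, 3 were already in the fixed amino acid response list, whose lower values prompted the hypothesis. The 10 others were all lower, with a mean of -0.47 (SD 0.29), and differed from the non-targets by -0.57 (exact permutation p = 0.000154 over 19448 splits, two-sided), which is consistent with lower activity of that response in the EV-labelled libraries. Mitochondrial synthetase genes had 3 higher, LARS2, MARS2 and YARS2, and 0 lower of 16 (adjusted p = 0.547).

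Several genes often used to describe pancreatic carcinoma lines had 0 counts in all 6 libraries. They were the epithelial genes CDH1, EPCAM, CLDN3 and GRHL2, the mesenchymal cadherin genes CDH2 and CDH11, and the matrix gene SPARC. KRT7 had 1 to 10 counts per library. Whether the cells are the line that the labels name was not tested.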
